A study of Mus musculus with 6 samples.

How the data were processed

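RNA was sequenced from mouse pituitary glands in 6 libraries, 1 for each group. Per the labels' protocols, glands of mice carrying a Cre driver and a Cre-activated YFP reporter at the ROSA locus were pooled by genotype, dispersed with collagenase and sorted by FACS, and RNA was prepared from the fluorescent fraction. Nontransgenic glands were sequenced as the comparison. Per the labels' protocols, 250 ng of RNA entered a ribosomal RNA depletion method that captures both mRNA and long non-coding RNA (lncRNA). The adult animals were 7 weeks old and the young animals were at postnatal day 7 (P7). Groups were taken from the labels. The sex of the animals is not stated in the sources used here.

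The deposited files are isoform tables of Cufflinks, 1 per library, with a line for each transcript. FastQC, Bowtie2, Cufflinks and the genome build mm39 are named in the submitters' processing notes, without versions. Each deposited line gives the FPKM (fragments per kilobase of transcript, relative to all mapped fragments of the library) computed by the authors, the bounds of its interval, a status and the coverage. The deposited coverage signal was a constant multiple of FPKM within each file. That constant was used as a relative measure of depth: 3.10 in the adult Tshbcre library, 7.32 in the Ghcre library, 5.97 in the Lhbcre library, 2.68 in the adult whole gland, 3.08 in the P7 Tshbcre library and 3.24 in the P7 whole gland. The number of reads is not given in the sources used here. The files hold transcripts with RefSeq names and, per library, transcripts assembled without a name. Whether reads were counted by strand is not given in the sources used here, so a gene and an overlapping or antisense gene cannot be told apart, and near-identical copies such as Hba-a1 and Hba-a2 share reads.

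The table of the adult Ghcre library had 1048576 lines and ended within chromosome 5, at position 44957466. It listed 32923 gene names, against 49846 to 50316 in the other files. Genes it does not list were treated as not measured, and comparisons with this library are over the listed genes. Chromosomes covered to their end in every file numbered 14. Gh, Prl and Malat1 are also not listed in some of the other tables used here and were treated as not measured there.

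The value of a gene was the sum of the FPKM of its annotated transcripts, over all transcripts of a gene name. Each library was divided by 1 factor, the median of ratios to the geometric mean over the 5808 genes at 1 FPKM or more in all 6 libraries. The factors were 1.00, 0.758, 0.967, 1.10, 0.976 and 1.42 for adult Tshbcre, Ghcre, Lhbcre, adult whole, P7 Tshbcre and P7 whole. Biotypes came from the RefSeq and GENCODE annotations of the older build GRCm38, used for names and biotypes only: 35541 genes matched by accession, 13206 by symbol, 2 by synonym, 54 by GENCODE name and 1545 not at all. Coordinates are those of the files, on mm39, counted from 1.

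An FPKM of 0 was not taken as absence. There were 166 protein-coding genes listed at 0 in 1 library and at 5 or more in all the others, and for 127 of them the same file held an assembled transcript in the locus of the gene. Counts are therefore given both over all genes and over genes above 0 in each library compared, and again with the assembled transcripts of 200 nt or more added to the gene where a locus held 1 named gene. These counts and the addition were chosen after the data were examined. The addition is uneven between libraries: transcripts of 200 nt or more made up 65.8% of unnamed transcripts in the adult whole gland and 4.25% in the Lhbcre library. A change with assembled transcripts added was therefore not separated from the lengths of the transcripts assembled in each library.

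With 1 library per group there are no replicates, and no test, p-value or error between animals was computed. Comparisons are differences of log2(scaled FPKM + 1) between libraries. Folds are on that scale, which understates the difference of low genes. A gene was counted as apart when it differed at least 4-fold with the higher library at 1 scaled FPKM or more. The deposited bounds of FPKM cover the counting and assignment of reads within a library only. For each of 22 gene lists fixed before the data were examined, the median log2 difference of the members at 1 scaled FPKM or more in a library of the comparison was set among 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these libraries and is not a test of the conditions. On the adult whole gland simulated against itself, over 28355 genes, 98% of 100 genes set at 8-fold and 0% of 100 genes set at 3-fold were called with the right sign, and 1 of 28155 unchanged genes was called. A fold of 3 lies under the threshold of 4. The simulation drew counting noise only, over genes above 0 in the adult whole gland. It held no zeros from the assignment of reads, no loci left out and no difference between animals, so it gives no rate of false calls for these libraries. Of 300 simulated lists without a difference, 7% fell outside the central range of the random lists that should hold all but 5 in 100, and their median percentile was 44.7.

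The genes named by rank were fixed before the data were examined: the 6 protein-coding genes and 5 lncRNA genes furthest apart in each direction, at 5 and 2 scaled FPKM or more, and 6 of each kind for a sorted library against both other adult sorted libraries. Applied as written, that rule names 167 genes, of which 153 are listed at 0 in a library compared, and 77 of those are no longer apart once assembled transcripts are added. The rule was therefore applied to genes above 0 in every library compared, which names 123, with 14 in both sets. That departure was made after the data were examined. Members of the lists are named whatever their values.

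Alternatives fixed before the data were examined were FPKM with no factor, libraries scaled to an equal sum over annotated genes of 200 nt or more, a pseudocount of 0.1, no minimum or a minimum of 5, the highest transcript per gene, only transcripts of status OK and 200 nt or more, only genes whose summed bounds do not overlap, the mean of the other sorted libraries, and a stricter overlap of unnamed loci. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.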

Results

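Transcripts were profiled in cells sorted from mouse pituitary glands by the lineage of 3 hormone genes, and in whole glands, at 2 ages. The series addresses long non-coding RNAs in pituitary development and in specific cell types. The sorted libraries came from 42 adult Tshbcre glands, 12 adult Ghcre glands, 7 adult Lhbcre glands and 5 Tshbcre glands at P7. The whole-gland libraries came from 1 adult gland and from 8 glands at P7. Each group was 1 library, so no value has a replicate and no difference was tested. Depth, relative to the adult whole gland, was 1.16 in the adult Tshbcre library, 2.73 in the Ghcre library, 2.23 in the Lhbcre library, 1.15 in the P7 Tshbcre library and 1.21 in the P7 whole gland. Genes at 1 scaled FPKM or more numbered 13852, 9552, 13986, 13907, 13843 and 13836 in adult Tshbcre, Ghcre, Lhbcre, adult whole, P7 Tshbcre and P7 whole. The Ghcre table ended within chromosome 5, so its number covers part of the genome.

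The driver genes were examined first. Tshb, which encodes the beta subunit of thyrotropin (chromosome 3, 102684621 to 102718175, mm39), stood at 1075 scaled FPKM in the adult Tshbcre library, with deposited bounds of 1028 and 1122, and at 3001 in the P7 Tshbcre library, with bounds of 2874 and 3127. It stood at 33.1 in the adult whole gland, 61.0 in the P7 whole gland, 9.05 in the Lhbcre library and 3.87 in the Ghcre library. Lhb, which encodes the beta subunit of luteinizing hormone (chromosome 7, 45066912 to 45071279), stood at 2198 in the Lhbcre library and 637 in the adult whole gland. Its level was 2904 in the adult Tshbcre library. Lhb lies past the end of the Ghcre table. Gh, the growth hormone gene (chromosome 11, 106191087 to 106194529), is not listed in the Ghcre, Lhbcre and adult whole tables used here, so the driver gene could not be checked in the Ghcre library. Gh was at 14806 in the adult Tshbcre library, 3870 in the P7 Tshbcre library and 6032 in the P7 whole gland.

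**Figure D1:**
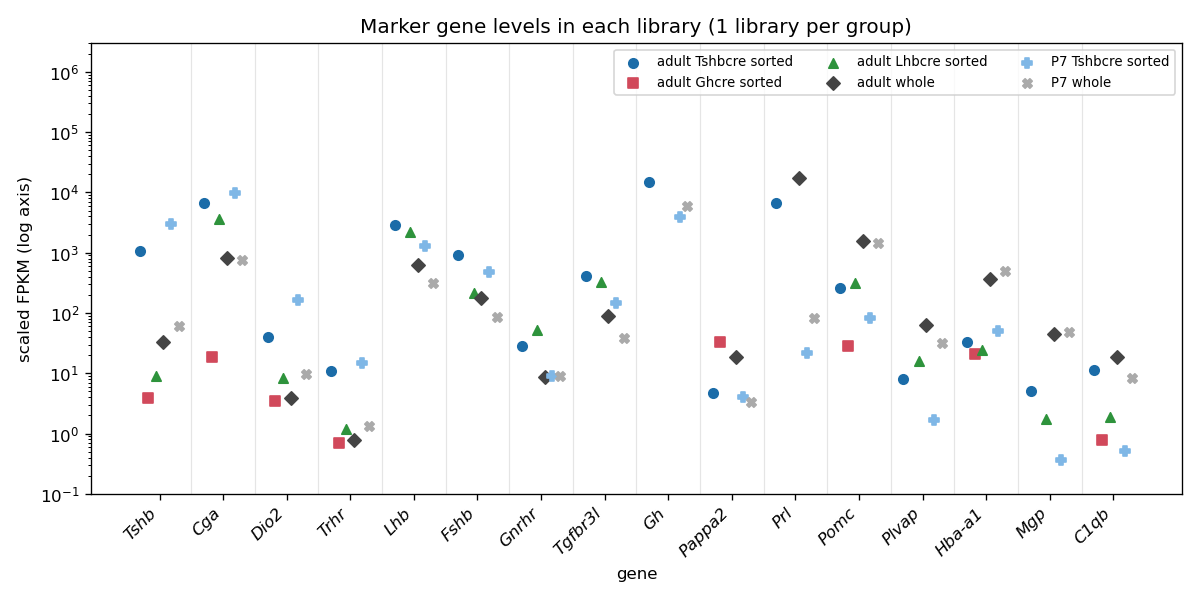
Scaled FPKM on a log axis for 16 marker genes, 1 point per library and no point where a gene is listed at 0 or not listed. Tshb is at 1075 and 3001 in the Tshbcre libraries and at 61.0 or less in the others, and Prl is at 17579 in the adult whole gland and 82.5 in the P7 whole gland.

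The adult Tshbcre library was compared with the adult whole gland to describe the sorted thyrotropin lineage. Genes of thyrotropes, the cells that make thyrotropin, were higher in the sorted library. Of 10 measured members of the thyrotrope list, 7 were at least 4-fold higher and none was 4-fold lower, and the median log2 difference of 2.52 lay at percentile 100 of the random lists. Tshb was 31.5-fold higher. Dio2, a deiodinase that activates thyroid hormone, was 8.49-fold higher, at 40.4 against 3.87 scaled FPKM. Trhr, the receptor for thyrotropin-releasing hormone, was 6.63-fold higher, and Cga, the alpha subunit shared by the glycoprotein hormones, stood at 6546 against 805, or 1289 with assembled transcripts added. Genes of gonadotropes, the cells that make luteinizing and follicle-stimulating hormone, were also higher: 8 of 15 measured members were 4-fold higher, with a median of 2.01 at percentile 100. Lhb was 4.55-fold higher and Fshb 5.12-fold higher, at 928 against 180. This list shares Cga, Foxl2, Gata2 and Isl1 with the thyrotrope list, and Foxl2 is listed at 0 in the adult whole gland.

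Genes of dense-core secretion had a median of 0.50, at percentile 99.99, with Chga, a granin of secretory granules, 9.37-fold higher and Scg2 7.16-fold higher. With assembled transcripts added, Chga stood at 1155 against 235 and Scg2 at 1391 against 328. Markers of other cells were lower. Endothelial genes had a median of -2.05 with 6 of 12 members 4-fold lower, and mesenchymal and pericyte genes a median of -2.08 with 6 of 10 members 4-fold lower, both at percentile 0. Plvap, an endothelial gene, was 7.05-fold lower, at 8.09 against 63.1, and Mgp, a gene of mesenchymal cells, was 7.33-fold lower. Erythroid genes had a median of -3.13, at percentile 0, and Hba-a1, an alpha globin gene, was 10.5-fold lower, although its reads cannot be told from those of Hba-a2. Hbb-bt was 8.73-fold lower. Genes of corticotropes had a median of -1.66, at percentile 0.08, and Pomc, the precursor of corticotropin, was 5.95-fold lower. Melanotrope genes had a median of -1.96 and lactotrope genes a median of -1.13, at percentiles 0.01 and 0.02. Prl, the prolactin gene, still stood at 6546 against 17579, above the Tshb level of 1075 in the sorted library. Gh also stood above Tshb there, and is not listed in the adult whole gland. Somatotrope genes, at -0.90, and genes of the posterior lobe, at -1.23, lay at percentiles 0.16 and 1.26. Stem and folliculostellate genes had a median of -0.77 at percentile 0.02, with none of 15 members 4-fold lower. Immune genes had a median of -0.59, at percentile 0.49. C1qb, a complement gene of macrophages, stood at 11.2 against 18.8. Immediate early and heat shock genes had a median of -0.53, at percentile 0.01.

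Further protein-coding genes far apart in this comparison were Cck, the cholecystokinin gene, at 20.7 against 0.41 and 15.4-fold higher, and Kcnk3, a potassium channel gene, 11.2-fold higher, which stood at 15.8 against 2.90 with assembled transcripts added. Syngr1 was 8.67-fold higher and Csrp1 7.76-fold lower on annotated transcripts, and neither remained 4-fold apart with assembled transcripts added. Among lncRNA genes, 20 were higher and 20 lower, and 5 and 1 of these were above 0 in both libraries. Foxl2os, next to the transcription factor gene Foxl2 (chromosome 9, 98831208 to 98837363), stood at 24.7 against 1.59 and was 9.91-fold higher, and with assembled transcripts added it stood at 32.8 against 7.10. 4933430M04Rik (chromosome 11, 24431909 to 24519951) stood at 3.55 against 0.10 and was 4.15-fold higher, and with assembled transcripts added it stood at 6.85 against 0.10. Meg3, Gm31623, Gm40155 and B930095G15Rik were apart on annotated transcripts, and not with assembled transcripts added. Meg3 then lay lower in the sorted library, with a log2 difference of -0.45. The list of known lncRNA genes had a median of -0.09, at percentile 27.1, and of 0.067 over genes above 0 in both.

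Over the 15797 genes compared, 509 were 4-fold higher in the adult Tshbcre library and 606 lower. Of these genes, 81.7% were listed at 0 in 1 of the libraries, and over genes above 0 in both the counts were 90 and 114, of which 68 and 67 also held with assembled transcripts added. The share of higher genes was 45.7% with the scaling used here, 51.3% when libraries were scaled to an equal sum over annotated genes and 50.3% with assembled transcripts added.

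The adult Ghcre library was compared with the adult whole gland over the 11286 genes at 1 scaled FPKM or more that its table lists. Genes of corticotropes, gonadotropes and non-endocrine cells were lower. Pomc was 53.8-fold lower, at 27.9 against 1555, and Cga was 40.9-fold lower, at 18.7 against 805. The gonadotrope list had a median of -1.81 with 4 of 8 measured members 4-fold lower, at percentile 0.01, and corticotrope genes a median of -2.16 at percentile 0.13, with 3 of 5 members 4-fold lower and 1 higher. The latter was Crhbp, which encodes a binding protein of corticotropin-releasing hormone, at 4.22 against 0.14. The thyrotrope list had a median of -0.11, at percentile 34.0, and Tshb was 7.01-fold lower. The lactotrope list had a median of -0.044, at percentile 45.2. Somatotrope genes had a median of 0.05 over 7 measured members, at percentile 52.9, with none 4-fold higher and 1 lower. That member was Foxo1, a forkhead transcription factor gene, at 1.46 against 10.5, and at 11.2 against 10.5 with assembled transcripts added. Pappa2, a protease of insulin-like growth factor binding proteins, stood at 32.8 against 18.7 and Neurod4, a transcription factor gene, at 15.8 against 5.07. Pou1f1, the transcription factor shared by somatotropes, lactotropes and thyrotropes, stood at 40.3 against 39.0.

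Immune genes had a median of -2.84 with 7 of 9 members 4-fold lower, and C1qb stood at 0.79 against 18.8. Endothelial genes had a median of -2.81, mesenchymal genes a median of -2.53 and erythroid genes a median of -3.98, the last over 2 members. Genes of the melanotrope, stem and posterior lobe lists had medians of -2.10, -1.68 and -1.83. Dense-core secretion genes had a median of -0.67, at percentile 0.43. Scaled to an equal sum over annotated genes it was 0.67, so its direction depends on the scaling. Less the median of all measured genes it was -0.67 and -0.59 under these scalings, a subtraction that largely cancels the factors. Igfbp5, Timp3 and Igfbp3 were 19.5-fold, 16.9-fold and 16.4-fold lower, and Gstm1, a glutathione transferase gene, was 17.7-fold lower, at 7.07 against 53.7 with assembled transcripts added. Nkiras1, which overlaps Ube2e1, was 7.18-fold higher, and Arsb, a lysosomal sulfatase gene, was 5.47-fold higher at 73.1 against 12.5. Klf7, Socs3, Snrnp48 and Hypk were 4-fold higher on annotated transcripts, and not with assembled transcripts added. Of the heat shock genes, Hspa1a stood at 417 against 177, and its copy Hspa1b at 398 against 172.

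Among lncRNA genes, 33 were higher and 12 lower in the Ghcre library, and 5 and 2 of these were above 0 in both. 1700122H20Rik (chromosome 17, 7163339 to 7169117) stood at 8.04 against 0.16, Gm1604a, which overlaps Rsph3a and Tagap, at 24.3 against 3.74, and Gm39903 (chromosome 2, 107559859 to 107629672) at 5.49 against 0.61. Gm51921 (chromosome 11, 103955935 to 103965529) was 11.5-fold lower, at 26.3 against 312. LOC115487747 and Six3os1 did not stay 4-fold apart with assembled transcripts added. Counts were 501 genes higher and 605 lower, of which 418 and 412 were listed at 0 in 1 library. They were 83 and 193 over genes above 0 in both. The share of higher genes was 45.3% with the scaling used here, 35.4% with FPKM as deposited and 80.4% when libraries were scaled to an equal sum over annotated genes, which moved the median log2 ratio of all genes to -0.55 and 1.33.

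The adult Lhbcre library was compared with the adult whole gland to describe the gonadotropin lineage. Gonadotrope genes had a median log2 difference of 1.07 over 14 measured members, at percentile 100, with 3 members 4-fold higher and none 4-fold lower. Nr5a1, the nuclear receptor gene that marks gonadotropes, was 9.29-fold higher, at 55.5 against 5.08. Gnrhr, the receptor for gonadotropin-releasing hormone, was 5.60-fold higher, Cga stood at 3649 against 805, Tgfbr3l was 3.56-fold higher and Lhb was 3.45-fold higher. Fshb stood at 216 against 180. The thyrotrope list had a median of 0.28, at percentile 83.4, and Tshb was 3.40-fold lower. With assembled transcripts added, Nr5a1 stood at 55.5 against 9.16 and Cga at 3649 against 1289, the latter no longer 4-fold apart. Dense-core secretion genes had a median of 0.86, at percentile 99.99, and Scg2 was 5.04-fold higher, but with assembled transcripts added it stood at 980 against 328. Neurod1, a transcription factor gene on the corticotrope list, stood at 6.05 against 0.33, or 1.24 with assembled transcripts added, while that list had a median of -1.12, at percentile 0.86.

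Stem and folliculostellate genes were lower in the Lhbcre library, with a median of -1.58 and 6 of 16 members 4-fold lower, at percentile 0. Cyp2f2, a cytochrome gene on this list, was 15.8-fold lower. Endothelial genes had a median of -1.34, mesenchymal genes a median of -2.12, immune genes a median of -1.86 and erythroid genes a median of -3.45, all at percentile 0. Mgp was 16.4-fold lower and Apod 10.7-fold lower. The lactotrope, somatotrope, melanotrope and posterior lobe lists had medians of -0.94, -1.01, -1.08 and -1.27. Genes far higher in this library were Xkrx at 48.7 against 0.55, Reln, which encodes the secreted protein reelin, at 19.9 against 0.26, Aebp1 at 63.9 against 3.34, Slurp2 at 18.7 against 0.66 and Crtac1 at 26.7 against 1.42. Aebp1 overlaps Pold2. Polr2j was 11.5-fold higher on annotated transcripts only.

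Xist, the lncRNA transcribed from the inactive X chromosome of female cells (X, 102503979 to 102526839), stood at 29.4 in the Lhbcre library and 0.06 in the adult whole gland. The Y-linked genes Ddx3y, Kdm5d and Eif2s3y stood at 0.01, 0.01 and 0.50 in the Lhbcre library and at 2.61, 3.04 and 10.3 in the adult whole gland. In the adult Tshbcre library Xist stood at 0.11 and Ddx3y at 3.20. The Lhbcre library therefore differed from the adult Tshbcre and adult whole libraries in markers of sex as well as of lineage, and the Ghcre table lists none of these genes. Among lncRNA genes, 63 were higher and 17 lower, and 12 and 1 of these were above 0 in both libraries. Foxl2os was 14.8-fold higher, at 37.3 against 1.59, or 7.10 with assembled transcripts added. Gm35664 (chromosome 10, 76797975 to 76798436) stood at 5.31 against 0.25, and Gm46178 (chromosome 1, 190853099 to 190859201) at 13075 against 1989. Gm51921 was 9.77-fold lower. Meg3 was 7.05-fold higher on annotated transcripts, and its log2 difference was -0.85 with assembled transcripts added. The addition raised Meg3 from 127 to 1622 in the adult whole gland and left it at 902 in the Lhbcre library. Few unnamed transcripts of the Lhbcre library reached the 200 nt needed to be added. In total 633 genes were higher and 898 lower, 77.3% of them listed at 0 in 1 library, and 162 and 185 were so among genes above 0 in both. The share of higher genes was 41.3% with the scaling used here and 58.9% when libraries were scaled to an equal sum over annotated genes.

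At P7 the Tshbcre library was compared with the P7 whole gland. Thyrotrope genes had a median of 1.69, at percentile 100, with 4 of 11 measured members 4-fold higher and 1 lower. Tshb was 48.4-fold higher, Dio2 15.6-fold higher at 164 against 9.59, and Trhr 6.64-fold higher, and Cga stood at 9593 against 749. Foxl2 is listed at 0 in the P7 Tshbcre library. Gonadotrope genes had a median of 0.19, at percentile 87.0, with 3 of 15 members 4-fold higher and 2 lower. Over genes above 0 in both the median was 0.70, with 3 members 4-fold higher and none lower, and with assembled transcripts added it was 0.79. Lhb was 4.09-fold higher and Fshb 5.60-fold higher, while Gnrhr stood at 8.91 against 9.17. Nr5a1 is listed at 0 in the P7 Tshbcre library and stood at 6.09 in the P7 whole gland, and with assembled transcripts added it stood at 11.03 against 12.7. Dense-core secretion genes had a median of 0.98, at percentile 99.99, and Chgb was 8.60-fold higher and Pcsk1, a prohormone convertase gene, 6.76-fold higher.

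All 12 endothelial genes and all 11 measured mesenchymal genes were 4-fold lower in the P7 Tshbcre library, with medians of -2.85 and -3.46. Mgp was 36.6-fold lower, and Col1a1 and Col3a1, which encode fibrillar collagens, were 26.8-fold and 22.5-fold lower. Dcn, Igfbp4 and Nid1 were 24.8-fold, 22.5-fold and 18.8-fold lower. Stem and folliculostellate genes had a median of -1.78 and immune genes a median of -2.09. Proliferation genes had a median of -0.87, at percentile 0.04, with 2 of 20 members 4-fold lower, and Top2a, a topoisomerase of dividing cells, stood at 4.61 against 10.5. Transcription factor genes of the pituitary had a median of -1.24, at percentile 0, with 7 of 31 members 4-fold lower and 1 higher. Corticotrope, melanotrope, lactotrope, somatotrope, erythroid and posterior lobe genes had medians of -1.47, -1.69, -0.81, -0.58, -3.17 and -1.38. Cck was 18.6-fold higher and Prss28, a serine protease gene, was 16.9-fold higher. With assembled transcripts added, Cck stood at 32.8 against 0.34 and Prss28 at 50.3 against 0.74. Sycp1, a gene of meiosis that follows Tshb on chromosome 3 (102725815 to 102843416), stood at 14.0 against 0.05, or 30.6 against 0.05 with assembled transcripts added. In the adult Tshbcre library Sycp1 stood at 15.1, and it is listed at 0 in the adult whole gland. Nap1l5 was 12.9-fold higher on annotated transcripts only.

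Among lncRNA genes, 57 were higher and 22 lower in the P7 Tshbcre library, and 15 and 2 of these were above 0 in both. LOC108168764, which lies within the span of Stk39 (chromosome 2, 68080001 to 68083244), stood at 10.6 against 0.19. Gm33551 (chromosome 3, 10913955 to 10922597) stood at 7.73 against 0.37 and Gm48606 (chromosome 12, 16282446 to 16337544) at 17.4 against 2.10. With assembled transcripts added, Gm48606 stood at 179.5 against 2.10. H19, an imprinted lncRNA, was 6.29-fold lower and Snhg3, a host gene of small nucleolar RNAs, 4.58-fold lower. 1300002E11Rik and A230057D06Rik did not stay 4-fold apart with assembled transcripts added. Known lncRNA genes had a median of 0.37, at percentile 99.5. With FPKM as deposited it was -0.10, so its direction depends on the scaling. Less the median of all measured genes it was 0.38 and 0.37 under these scalings, a subtraction that largely cancels the factors. In total 534 genes were higher and 1001 lower, 70.3% of them listed at 0 in 1 library, and 138 and 318 over genes above 0 in both. The share of higher genes was 34.8% with the scaling used here, 24.6% with FPKM as deposited and 40.1% when libraries were scaled to an equal sum over annotated genes. With assembled transcripts added it was 46.3%, from 615 genes higher and 713 lower.

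**Figure D2:**
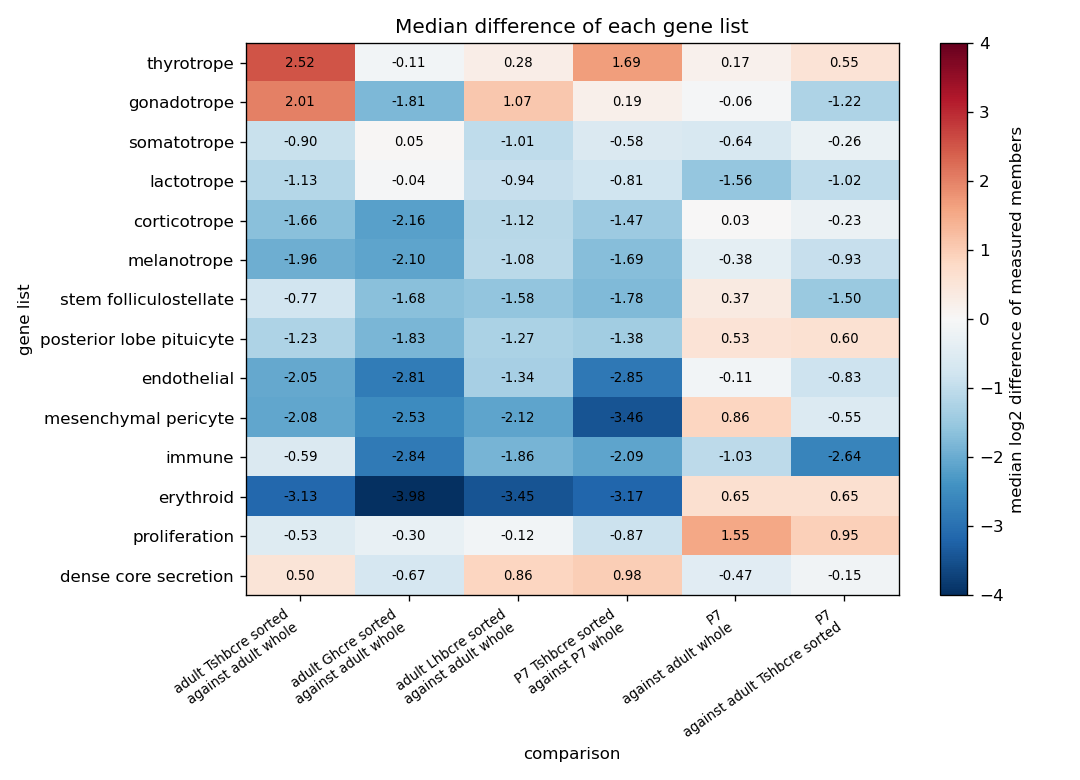
Median log2 difference of 14 cell type and process gene lists (lines of the grid) in 6 comparisons (columns), each cell giving the median of the measured members, with red for higher and blue for lower in the library named first. The thyrotrope list is at 2.52 and 1.69 in the adult and P7 Tshbcre comparisons, and the erythroid list is at -3.13 to -3.98 in the 4 comparisons of a sorted library with a whole gland.

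The whole glands at P7 and in the adult were compared to describe development. Proliferation genes were higher at P7, with a median of 1.55 at percentile 100 and 5 of 20 members 4-fold higher. Top2a was 6.06-fold higher, or at 10.5 against 2.07 and under 4-fold with assembled transcripts added, and Mki67, the gene of the proliferation antigen Ki-67, 4.88-fold higher, at 10.1 against 1.27. The mesenchymal list had a median of 0.86, at percentile 99.98, with 4 of 11 members 4-fold higher. Eln, which encodes elastin, was 18.4-fold higher at 34.6 against 0.94, Col1a1 was 5.12-fold higher, and Mfap2, Acta2 and Fbn2 were 7.15-fold, 7.13-fold and 6.69-fold higher. With assembled transcripts added, Eln stood at 34.6 against 2.70, Mfap2 at 29.3 against 6.24 and Fbn2 at 7.86 against 1.10. H2bc6, a histone gene, was 7.85-fold higher, and Col6a3 was 7.50-fold higher on annotated transcripts only. Prl, the prolactin gene (chromosome 13, 27241553 to 27249187), stood at 82.5 at P7, with deposited bounds of 77.3 and 87.7, and at 17579 in the adult, with bounds of 16851 and 18307, a 210-fold difference. The lactotrope list had a median of -1.56, at percentile 0.01.

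Immune genes were lower at P7, with a median of -1.03 at percentile 0.01. H2-Aa and Cd74, which act in antigen presentation, were 11.5-fold and 10.7-fold lower. Cyp2f2, Ecel1 and Lcn2 were 26.3-fold, 15.3-fold and 11.4-fold lower. The stem and folliculostellate list had a median of 0.37, at percentile 97.8, which turned to -0.14 with a minimum of 5 scaled FPKM. Within it Rbpms stood at 60.5 against 10.98 and Sox2 at 14.1 against 6.95, and Cyp2f2 and Lcn2 were lower. Immediate early and heat shock genes had a median of 0.46 and erythroid genes a median of 0.65, at percentiles 99.9 and 99.1. Thyrotrope, gonadotrope, corticotrope and endothelial genes had medians of 0.17, -0.06, 0.03 and -0.11, at percentiles 77.5, 35.4, 49.6 and 25.9. Dense-core secretion genes had a median of -0.47 and somatotrope genes a median of -0.64. Melanotrope and posterior lobe genes had medians of -0.38 and 0.53.

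The imprinted list had a median of 0.12 with 5 of 21 members 4-fold higher and 1 lower at P7, and of -0.013 over genes above 0 in both. H19 was 15.1-fold higher at P7, at 18.2 against 0.27, and Igf2, the growth factor gene next to it, was 5.57-fold higher. Xist was 17.0-fold higher at P7, at 17.0 against 0.06, while Ddx3y stood at 2.12 against 2.61. The whole glands therefore differed in Xist, a marker of female cells, as well as in age. LOC108168764 was 4.42-fold lower and Gm29932 4.21-fold lower at P7. Firre and LOC115489499 did not stay 4-fold apart with assembled transcripts added. Counts were 520 genes higher at P7 and 514 lower, 84.3% of them listed at 0 in 1 library, 384 and 472 with assembled transcripts added, and 72 and 90 over genes above 0 in both. Among lncRNA genes, 19 were higher and 26 lower, with 3 and 4 above 0 in both.

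The Tshbcre libraries of P7 and the adult were compared to follow the sorted lineage with age. Thyrotrope genes had a median of 0.55, at percentile 99.4, with none of 11 members 4-fold higher and 1 lower, Foxl2, which is listed at 0 at P7. Dio2 stood at 164 at P7 and 40.4 in the adult, just under that threshold, and Tshb was 2.79-fold higher. Cga stood at 9593 against 6546. Gonadotrope genes had a median of -1.22, at percentile 0: Gnrhr was 2.96-fold lower, Tgfbr3l 2.81-fold lower, Lhb 2.27-fold lower and Fshb 1.92-fold lower. Prl was 289-fold lower, at 21.7 against 6546, and Gh 3.83-fold lower. Genes of other cell types stood at a median of 25.3% of their whole-gland level in the adult Tshbcre library and 8.09% in the P7 one. Their age differences here were not separated from how much of other cells each sorted library held. The age differences of thyrotrope and gonadotrope genes were not separated from that share either. Immune genes had a median of -2.64, with 5 of 9 members 4-fold lower, at percentile 0. Cd74 was 12.1-fold lower, Lyz2, a macrophage lysozyme gene, 11.9-fold lower and Apoe 10.9-fold lower. Stem and folliculostellate genes had a median of -1.50, and Cyp2f2 stood at 0.37 against 33.2. Proliferation genes had a median of 0.95, at percentile 99.8, and Top2a was 3.36-fold higher.

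Ecel1, an endopeptidase-like gene, was 16.2-fold lower in the P7 Tshbcre library. Atp5k stood at 71.9 against 2.84, Cartpt, a neuropeptide gene, was 7.46-fold higher, and Frg1 6.56-fold higher, and Rbx1, Gng4 and Mrpl52 were so on annotated transcripts only. Xist stood at 62.6 at P7 and 0.11 in the adult and Ddx3y at 2.09 and 3.20, so these libraries also differed in this marker as well as in age. Gm51914, which overlaps Vmp1, stood at 12.8 against 0.20, LOC108168764 at 10.6 against 0.56 and Gm34259 (chromosome 17, 4662641 to 4683795) at 4.94 against 0.17. B930095G15Rik and Gm40155 were apart on annotated transcripts only. Counts were 573 genes higher at P7 and 743 lower, 86.1% of them listed at 0 in 1 library, and 87 and 96 over genes above 0 in both. Among lncRNA genes, 52 were higher and 21 lower, with 9 and 1 above 0 in both.

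The age differences of the Tshbcre libraries and of the whole glands share no library. Over 13977 genes above 0 in all 4 libraries and at 1 scaled FPKM or more in any, they had a Pearson correlation of 0.26 and a Spearman correlation of 0.24, both across genes, which are not independent replicates. Genes higher at P7 in both comparisons numbered 4, where independent lists would share 0.26, and genes lower in both numbered 10, where independent lists would share 0.42. The former were Cartpt, Gm42186, H3c3 and Xist. The latter included Prl, Cyp2f2, Ecel1, Cd74, H2-Aa, H2-Ab1 and Ly6a. Prl, Cyp2f2 and Cd74 are on lists of other cell types, whose genes were at a higher share of the whole-gland level in the adult than in the P7 Tshbcre library. H2-Aa, H2-Ab1, Ly6a and Ecel1 are on no list, so the cells they came from were not described. Xist, a marker of female cells, was higher at P7 in both comparisons. The overlap was therefore not separated from the share of other cells or from the sex of the pools. A further 4 genes were apart in opposite directions, where independent lists would share 0.67: LOC108168764 and the small RNA gene Gm23709 were higher at P7 in the Tshbcre library and lower in the whole gland, and Rbpms and the small RNA gene Gm25101 the reverse. These genes are named because the counts are small, and were chosen after their values were seen.

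Each adult sorted library was then compared with the higher of the other 2 over the 12079 genes listed in all 3 tables. In the Tshbcre library 260 genes were 4-fold above both others, 33 of them above 0 in each. Tshb was 107-fold higher, Hecw2 11.2-fold, at 35.5 against 4.53 with assembled transcripts added, Grin3a, a glutamate receptor subunit gene, 5.95-fold, C1qc 5.64-fold and Igfbp5 5.50-fold higher, and the lncRNA Gm51921 5.78-fold higher. Pcbp2 was so on annotated transcripts only. Igfbp5 and Gm51921 stood at 148 and 184 in the Tshbcre library and at 164 and 312 in the adult whole gland. They were therefore not higher in this library than in unsorted cells. Thyrotrope genes had a median of 1.04 over 8 members, stem and folliculostellate genes a median of 1.27 and immune genes a median of 1.11, at percentiles 100, 99.99 and 100. Gonadotrope genes had a median of 0.51 there, at percentile 99.92, and of 0.18 over genes above 0. Against the adult whole gland, the stem and immune lists were lower in the Tshbcre library, as given above. In the Ghcre library 291 genes were 4-fold above both others, of which 4 were above 0 in each. Dnah9 alone met the naming rule there, at 7.40 against 0.75, and did not stay 4-fold higher with assembled transcripts added. Somatotrope genes had a median of 0.31, at percentile 98.6, and of -0.054 with FPKM as deposited, so the direction depends on the scaling. Less the median of all measured genes these medians were 0.57 and 0.50, a subtraction that largely cancels the factors. The Lhbcre library had 154 such genes, 12 of them above 0 in each. Adcy8, an adenylyl cyclase gene, was 6.95-fold higher, Gal, the galanin gene, 6.80-fold, Nhlh2, a transcription factor gene, 5.89-fold, Rnd3 5.70-fold, Pgf 5.12-fold and Aebp1 5.02-fold higher. Gonadotrope genes had a median of -0.81 in that comparison, at percentile 1.30, and the median was 0.016 against the mean of the others. Members that the Ghcre table does not list, Lhb among them, are not in these medians. Against the adult whole gland the gonadotrope list was higher in the Lhbcre library, as given above. The lists that lay highest in the Lhbcre library against both others were endothelial, melanotrope and corticotrope genes, with medians of 0.77, 0.55 and 0.55 at percentiles 99.89, 98.15 and 98.95. Without the Ghcre library, whose table covers part of the genome, the counts were 810 for Tshbcre and 707 for Lhbcre.

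Other lists were described in the same way. Transcription factor genes of the pituitary had a median of -0.43 in the adult Tshbcre library against the whole gland, which turned to 0.027 with assembled transcripts added, and a median of -0.95 in the Ghcre library, which was 0.18 when libraries were scaled to an equal sum over annotated genes. Less the median of all measured genes, the latter pair was -0.95 and -1.08, a subtraction that largely cancels the factors. In the Lhbcre library the median was -0.23. The imprinted list had medians of -0.54, -0.30 and -0.45 in the adult Tshbcre, Ghcre and Lhbcre libraries against the whole gland, and that of the Ghcre library was 0.089 over genes above 0 in both. Small structured RNAs had medians of -0.50, 1.19 and 0.10 in the same comparisons, and Rpph1, the RNA of ribonuclease P, stood at 29165 in the Ghcre library and 8404 in the adult whole gland. The 3 genes at the reporter locus had a median of -0.86 in the adult Tshbcre library and 2.51 in the P7 Tshbcre library, each against its whole gland. The latter turned to -0.9998 over the only member above 0 in both, Setd5, and the ROSA26 transcript itself is listed at 0 in the adult Tshbcre library and the P7 whole gland. The sex-linked list had medians of -0.29 and -1.83 in the adult Tshbcre and Lhbcre libraries against the whole gland. The first was 0.067 over genes above 0 in both, and the latter 0.97 with a minimum of 5 scaled FPKM. Of the mitochondrial list only mt-Rnr1 was found by name, in the P7 whole gland.

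Transcripts without an annotated name were counted per library. They numbered 463893 in the adult Tshbcre library, 953764 in the Ghcre table, 651575 in the Lhbcre library, 277846 in the adult whole gland, 682159 in the P7 Tshbcre library and 273226 in the P7 whole gland. Transcripts under 60 nt made up 6.42%, 41.4%, 76.7%, 2.34%, 49.3% and 5.68% of these, in the same order, and transcripts of 200 nt or more made up 51.9%, 16.7%, 4.25%, 65.8%, 13.8% and 52.2%. Outside the spans of annotated genes lay 6.10%, 30.3%, 14.3%, 5.30%, 8.68% and 7.97%. Overlap was taken only over the 14 chromosomes covered to their end in every file. On these, the loci overlapped such a locus of another library by at least 1 base in 94.7%, 60.6%, 82.3%, 97.8%, 87.5% and 94.5% of cases. Over transcripts of 200 nt or more the shares were 90.4%, 85.1%, 96.0%, 93.7%, 94.3% and 91.1%. The overlap expected from random positions was not computed.

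Spliced unnamed loci of 200 nt or more and, as deposited, 1 FPKM or more outside annotated spans numbered 85 over the libraries, of which 56 were found in 1 library and 5 in 4. One locus on chromosome 2 (26146628 to 26159016), between Gm52504 and Ccdc187, stood at 206 scaled FPKM in the Lhbcre library, 46.0 in the Ghcre library, 43.7 in the P7 Tshbcre library and 7.01 in the adult Tshbcre library. Another on chromosome 12 (109695898 to 109700204), between the imprinted genes Rian and Mirg, stood at 77.3 in the Lhbcre library, 25.1 in the P7 Tshbcre library and 3.28 in the adult Tshbcre library. A locus on chromosome X (60216498 to 60219282), between Cdr1os and Cdr1, stood at 13.3 in the P7 Tshbcre library, 2.89 in the adult Tshbcre library, 1.87 in the adult whole gland and 1.25 in the P7 whole gland. These loci were singled out after their values were seen.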

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

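The tests below were all chosen only after the results they weigh were seen.

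Among members of the lists and genes named by rank that were above 0 in all 4 libraries, a gene was listed here when its age difference went opposite ways in the Tshbcre libraries and in the whole glands, by at least 2-fold in each, both on annotated transcripts and with assembled transcripts added. With 1 library per group, the difference between them was not tested. The log2 difference of P7 from adult in the Tshbcre libraries minus that in the whole glands was 5.04 for LOC108168764, a lncRNA within the span of Stk39, which stood at 10.6 and 0.56 in the P7 and adult Tshbcre libraries and at 0.19 and 4.27 in the P7 and adult whole glands. It was -4.40 for Rbpms, an RNA-binding protein gene, at 2.80 and 14.6 in the sorted libraries and 60.5 and 10.98 in the whole glands. It was -2.54 for Terc, the RNA of telomerase, at 0.35 and 2.72 against 3.56 and 1.16. It was -2.47 for Ier3, at 0.67 and 2.37 against 8.42 and 2.43.

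The first pattern weighed was that gonadotrope genes were higher in the adult Tshbcre library than in the whole gland. The 11 gonadotrope genes that are not on the thyrotrope list had a median log2 difference of 1.45, with 10 of them higher, and whole-gland cells left in the sorted fraction could bring them to the whole-gland level only by bringing the genes of other cell types there as well. Those genes stood at no more than a median of 29.2% of their whole-gland level under any scaling, with upper quartiles of 64.5% or less. The low medians of those lists were already known, so this outcome was fixed in advance and adds no support against such cells. The lowest median of the 11 genes under the other scalings was 1.37. Those scalings moved the median log2 ratio of all genes only to -0.16 and 0.19. They therefore argue against a scaling shift of that size and could not weigh a larger one. At P7 the same genes had a median of 0.13 with 7 of 11 higher, -0.33 with FPKM as deposited, where the median ratio of all genes was -0.55, and 0.13 with equal sums, so an effect of scaling on the sign at P7 cannot be told apart. Genes of other cell types reached a median of 8.09% at P7. That is too low for unsorted cells to hold the 11 genes at their whole-gland level, although the difference to be explained there is small. The low medians at P7 were also already known, so this adds no support either. Gonadotropes sorted along with thyrotropes, or cells with both sets of transcripts, cannot be told apart: the log2 ratios of the adult Tshbcre to the Lhbcre library ranged over 3.20, from Fshb at 2.10 to Nr5a1 at -1.09, but markers of sex also differed between those libraries. These ratios are on annotated transcripts only, and the range was not taken with assembled transcripts added.

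The next pattern was that loci of abundant hormones such as Gh and Prl are not listed in some of the tables used here. If genes were left out because of their own reads, those that are above 0 in the other complete files should rank high there by level times length, and the median percentile of these 46 genes was 99.94 among genes above 0, with 35 at 90 or more, although only 9 of 18 were so in the Lhbcre file. Taking runs of neighbouring genes as whole loci, the median percentile of the highest member was 99.92 over the 18 runs that hold a value in the other files, with 14 at 90 or more, and by file it ran from 69.2 over 4 runs in the P7 whole file to 100 over 8 runs in the Lhbcre file. Both readings are consistent with the medians over all files, that of whole loci not with the P7 whole file alone, and they are not told apart, and most genes not listed are at 0 in the other files, so that neither reading was tested for them. The adult Tshbcre file left out 5.85 times as many annotated transcripts as the P7 whole file at a depth ratio of 0.96. This argues against depth only for the number of transcripts not listed, and most genes not listed are at 0 in the other files. Genes not listed but above 0 in the other complete files numbered 8 in the adult Tshbcre file and 9 in the P7 whole file. In the deeper Lhbcre file they numbered 18, so whether depth bears on such genes cannot be told.

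The last pattern was the low level of Y-linked genes and the high level of Xist in the adult Lhbcre library. Y-linked reads assigned to assembled transcripts of 200 nt or more are argued against, since with those added the summed Y-linked level was 6.26% of the adult whole gland. On annotated transcripts that level was 6.40%, and Xist was 28.7-fold higher than in the adult whole gland. Transcripts of 200 nt or more made up 4.25% of the unnamed transcripts in the Lhbcre library. Reads assigned to shorter ones were not added, so they were not weighed. The sex of the pools is not stated in the sources used here and stays open, so differences of the Lhbcre library from the adult Tshbcre and adult whole libraries mix lineage with these markers of sex, which were not measured in the Ghcre library. Xist also stood at 62.6 and 17.0 in the P7 Tshbcre and P7 whole libraries against 0.11 and 0.06 in the adult ones, so age comparisons mix age with this marker.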

How the results depend on the processing

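The alternatives over genes above 0, with assembled transcripts added and without the Ghcre library were chosen after the data were examined. FPKM as deposited, no minimum, a minimum of 5, the highest transcript and assembled transcripts added each left all 15 gene counts within 1.5 times, and a stricter overlap left all 12 shares of unnamed loci within 1.5 times. Counts of genes higher and lower follow for adult Tshbcre, Ghcre, Lhbcre and P7 Tshbcre against whole, P7 against adult whole and P7 against adult Tshbcre, then genes above both others for Tshbcre, Ghcre and Lhbcre. Equal sums over annotated genes gave 1200 and 1137, 3744 and 913, 2204 and 1536, 1396 and 2088, 1187 and 938, 1441 and 1551, then 392, 1406 and 447. Those sums are over the genes each table lists, so the Ghcre table, which covers part of the genome, is not on a like footing there. A pseudocount of 0.1 gave 1075 and 1300, 1052 and 1309, 1638 and 1791, 1400 and 2054, 1067 and 1032, 1391 and 1519, then 450, 445 and 416, since low genes then reach larger folds. Genes above 0 gave 90 and 114, 83 and 193, 162 and 185, 138 and 318, 72 and 90, 87 and 96, then 33, 4 and 12, since fewer genes enter. With assembled transcripts added as well, they gave 125 and 93, 112 and 200, 188 and 172, 250 and 320, 61 and 101, 116 and 127, then 59, 23 and 28. Without that limit, assembled transcripts turned the balance to 431 and 426 in adult Tshbcre, 482 and 467 in Ghcre and 384 and 472 at P7 in the whole gland. Only transcripts of status OK and 200 nt or more moved 9 counts: 290 higher and 392 lower in adult Tshbcre, 235 higher in Ghcre, 512 lower in Lhbcre, 297 higher and 277 lower at P7 in the whole gland, 441 lower at P7 in Tshbcre, and 101 and 45 above both others in Tshbcre and Ghcre. Bounds that do not overlap moved 3, to 345 higher and 322 lower at P7 in the whole gland and 154 in Tshbcre above both others. Counts of lncRNA genes moved by more than 1.5 times in all 15 cases with equal sums, a pseudocount of 0.1 and genes above 0, in 14 with a minimum of 5 and in 10 with assembled transcripts added. Without the Ghcre library the latter counts of all genes were 810 for Tshbcre and 707 for Lhbcre, where more genes are listed and 1 library fewer has to be exceeded, and these were not separated.

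Among named genes and list medians outside the central 95% of their random lists, direction reversed for the following, and except as given above the cause was not tested. With assembled transcripts added, Meg3 was at -0.45 in adult Tshbcre and -0.85 in Lhbcre, and B930095G15Rik at 0.0029 in adult Tshbcre. With equal sums, the median was 0.001 for transcription factors in adult Tshbcre and 0.18 in Ghcre, 0.67 for dense-core secretion in Ghcre and -0.29 in Tshbcre against both others, 0.020 for the imprinted list in Lhbcre and 0.24 in Ghcre against both others. Assembled transcripts gave 0.027 for transcription factors in adult Tshbcre, the same value over genes above 0, and 0.22 and 0.38 for the imprinted list in Ghcre against both others, without and with that limit. A minimum of 5 gave 0.97 for the sex-linked list in Lhbcre and -0.14 for stem genes at P7 in the whole gland. FPKM as deposited gave -0.10 for known lncRNA genes in P7 Tshbcre and -0.054 for somatotrope genes in Ghcre against both others. Over genes above 0, without and with assembled transcripts added, the reporter locus had -0.9998 and -0.070 in P7 Tshbcre and 0.88 and 0.50 at P7 in the whole gland, and it did not reverse with assembled transcripts alone. Gonadotrope genes in Lhbcre had 0.016 against the mean of the others. Less the median of all measured genes, none of the 8 medians given here that turned under equal sums or FPKM as deposited turned sign. That outcome was close to fixed in advance, since 1 factor per library shifts a list and all genes nearly alike. It lends no support to either direction of these 8 medians. Without reversing, 101 of the 123 differences of named genes moved by more than their deposited bounds allow with equal sums, 91 with a pseudocount of 0.1, 52 with FPKM as deposited and 41 with assembled transcripts, and 52 list medians moved by more than the central range of their random lists allows with equal sums, 36 with a pseudocount of 0.1 and 30 with a minimum of 5. Medians inside that central range turned as well, among them over genes above 0 to 0.067 for the known lncRNA and the sex-linked list in adult Tshbcre, 0.089 for the imprinted list in Ghcre, and -0.057 and -0.013 for the thyrotrope and imprinted lists at P7 in the whole gland. Scaling moved the median log2 ratio of all genes to -0.16, -0.55, -0.19, -0.55, 0.39 and -0.01 with FPKM as deposited, and to 0.19, 1.33, 0.47, -0.03, 0.25 and 0.02 with equal sums, in the order of the comparisons above. Without read counts, the depth behind a single value is not known.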

Other observations

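No further tests were run for this part, and the genes named here were chosen after their values were seen. Malat1, an abundant nuclear lncRNA, stood at 1297 in the adult Tshbcre library, 997 in the adult whole gland, 1567 in the P7 Tshbcre library and 585 in the P7 whole gland, and is not listed in the Ghcre and Lhbcre tables used here. Neat1, the RNA of paraspeckles, stood at 4.87, 8.69, 6.69, 12.9, 3.46 and 3.55 in adult Tshbcre, Ghcre, Lhbcre, adult whole, P7 Tshbcre and P7 whole. Gas5, a host gene of small nucleolar RNAs, stood at 20.2, 94.9, 57.8, 66.7, 44.3 and 21.6 in the same order. Rian, an imprinted lncRNA next to Meg3, stood at 291 in adult Tshbcre, 340 in Lhbcre, 394 in adult whole, 361 in P7 Tshbcre and 209 in P7 whole.

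Foxl2, a transcription factor gene of thyrotropes and gonadotropes, is an example of a gene listed at 0 whose locus holds assembled transcripts in the same file, and the origin of such zeros was not tested. Its annotated transcript stood at 22.1 in the adult Tshbcre library and 6.24 in the P7 whole gland and is listed at 0 in the Lhbcre library, the adult whole gland and the P7 Tshbcre library. With the assembled transcripts of its locus added, the same libraries stood at 27.5, 9.23, 12.5, 4.63 and 18.8.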
